A study of Homo sapiens with 9 samples.

How the data were processed

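Only the processed table of the series was analysed; raw reads were not used here. Per the labels, RNA was taken from HL-60 parental, HRA and HRD cells in 3 biological replicates each, and stranded libraries of polyadenylated RNA were sequenced. The deposited notes name TopHat2 2.1.1, Bowtie2 2.3.5.1, Picard, Cufflinks 2.2.1, HTSeq 0.11.1 and DESeq2 with the human assembly hg19. The role and order of these tools, the annotation and the strand setting of the counting are not given.

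The signal in the table deposited by the authors is a read count per gene divided by a size factor of the library, for 20637 genes in 9 libraries. Every value was a whole multiple of 1 constant per library, within a tolerance of 0.001, so whole reads were recovered. Size factors recomputed from these reads by the median of ratios equalled those of the table. Reads recovered per library ran from 20822709 to 66563328. A value of 3 reads corresponds to 1.49 to 4.52 normalized reads, depending on the library, and 15360 to 17027 genes per library had reads. Between replicates the counts varied 15.3 to 60.3 times as much as counting error alone (chi-square per degree of freedom), so counting intervals cover counting error only and neither biological spread nor PCR duplicates.

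Genes with a value of at least 10 in at least 3 of 9 libraries were tested, which kept 12569 genes and 99.97% of the reads. A gene near 0 in parental cells passes this filter only through a group where it is higher. In lists of genes that parental cells hardly express, counts of risen genes therefore lean upwards. Values were transformed as log2(value + 1), and 1 linear model with all 9 libraries was fitted in limma 3.58.1 (R 4.3.3) with a variance trend. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes of a comparison, and a second count asked for at least a 2-fold change. Folds come from log2(value + 1), which understates those of genes with low values. Errors beside log2 fold changes are standard errors of the fit, whose median was 0.132, and errors beside means are standard deviations of 3 replicates. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so all p-values are those of the moderated model. The comparisons, the threshold, the filter, the gene lists, the rule for named genes and most of the other settings run were chosen before the data were examined.

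Gene lists were tested with camera using a correlation estimated from the residuals, adjusted over the 34 lists with at least 3 tested members. A preset correlation of 0.01 and the fry rotation test were alternatives. The 36 lists hold 926 distinct genes, of which 813 were in the table, 56 of them under an older symbol, and 650 were tested. Named genes are the 8 with the largest and the 8 with the smallest log2 fold change of each comparison that passed, had a mean of at least 100 in the higher group and no overlap between the groups, then 18 genes fixed beforehand and members of the lists with the smallest adjusted p. Clone names, pseudogenes and sex-chromosome marker genes were left out. Where a group had no read of a gene, the fold is a bound from a floor of 3 reads over the group, and where it had 1 to 3 reads it is a ratio of depth-scaled reads with an exact 95% counting interval.

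Gene types, chromosomes and the order of neighbours came from the RefSeq gene table of assembly GRCh38.p14, matched by symbol. No coordinates were taken from it because the counts were made on another assembly. It gave a type to 19655 genes, 12306 of them tested, and a place in the neighbour order to 11054 tested protein-coding genes. Stretches of a chromosome were found with running medians of 25 genes against limits from 100 shuffled gene orders. A stretch joins all windows past the limit and starting at most 25 genes apart, so its median over all genes can lie inside the limit.

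The replicate number was examined as a possible pairing. Deviations of same-numbered parental and HRA libraries correlated at 0.22, 0.38 and 0.14, and those of parental and HRD libraries at −0.08, 0.26 and 0.29. Those of HRA and HRD libraries correlated at −0.03, 0.41 and 0.23. A fit with the number as a block was therefore run. It is given beside the comparison of HRA with parental cells and, for the others, among the alternative settings. edgeR 4.0.16 with a quasi-likelihood fit and DESeq2 1.42.0 were run on the recovered reads. Python with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.

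In a simulated set with known changes among 12372 genes, the test recovered 46.3%, 86.6% and 98.5% of the 1.5-fold, 2-fold and 4-fold changes of the HRA comparison and 47.8%, 86.6% and 100% of those of the HRD comparison. The changes were set only in genes with a parental mean of at least 50, and no replicate effect was simulated. Recovery among genes with lower values is therefore not shown. Of 163 and 160 calls, 9 and 4 were false. A list of 30 genes raised 1.5-fold had an adjusted p of 4.91e-05, and 0 of 20 unchanged lists were called. Genes were drawn independently of each other there, while the real lists had estimated correlations of up to 0.870. The simulation therefore does not show how well the list test finds changes in correlated lists.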

Results

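Polyadenylated RNA was sequenced from HL-60 cells, a human acute myeloid leukaemia line of promyelocytic type, in a parental state and in lines resistant to either drug of standard induction chemotherapy. HRA cells are resistant to cytarabine (Ara-C), a deoxycytidine analogue that is phosphorylated inside the cell and then blocks DNA synthesis, and were kept in 100 nM of it. HRD cells are resistant to daunorubicin (DNR), an anthracycline that traps DNA topoisomerase II on DNA, and were kept in 30 nM of it. Each of the 3 groups had 3 biological replicates. Resistance and the presence of the drug in the medium were not separated by this design. The labels name only HRA cells for cytarabine and only HRD cells for daunorubicin. The replicates and p-values therefore cover the spread within each of these, not the spread over independently derived resistant lines. Changes particular to HRA or HRD cells cannot be told from changes of resistance. The parental libraries held 58534264, 27449119 and 20822709 reads in replicates 1, 2 and 3, and the HRA libraries 47537926, 25225828 and 26958509. The HRD libraries held 66563328, 22300023 and 28967118. Between 6.4% and 7.3% of the reads fell on the 10 most abundant genes of a library. The groups separated in a principal component analysis, in which component 1 (47.5% of the variance) set HRD apart and component 2 (23.2%) set HRA apart from parental cells. Component 3 (9.1%) held replicate 2 of every group away from the other replicates.

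To find the transcripts that accompany cytarabine resistance, HRA cells were compared with parental cells. SUCNR1, the receptor for succinate, rose by 4.46 on the log2 scale, from a normalized read count of 164 ± 22.4 to 3750.2 ± 1232 (SD, n = 3 in each group in all such values, adjusted p = 4.42e-06). CCNA1, a cyclin of meiotic cells that myeloid leukaemias also express, rose 13.6-fold, from 354 ± 144 to 4725 ± 1334. CACNB1, a calcium channel subunit, rose 14.5-fold from 16.2 ± 3.03 to 248 ± 33.6. The zinc finger gene ZNF704 rose 20.4-fold to 804 from 40.6 ± 15.3. ASS1, the enzyme that makes argininosuccinate on the way to arginine, fell 5.80-fold from 563 ± 112 to 96.1 ± 17.6 (adjusted p = 8.92e-05).

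Other genes with the largest rises in HRA were ADAM23 (log2 fold change 4.12 ± 0.38, SE), CNTNAP3B (3.89 ± 0.40), LPL (4.02 ± 0.56), which encodes lipoprotein lipase, and FBLN1 (3.71 ± 0.63). Parental replicate 3 decided the size of some of these changes. LPL stood at 169, 145 and 24.0 in the parental replicates and at 1384 ± 157 in HRA, and its log2 fold change was 3.13 without parental replicate 3. For FBLN1 the value was 4.44 without that library and 3.01 without parental replicate 2. The largest falls besides ASS1 were those of FSTL5 (−5.49 ± 0.76, with 7 reads left in the 3 HRA libraries), PTK7 (−3.55 ± 0.41), IGFBP2 (−3.49 ± 0.53), GIMAP6 (−2.90 ± 0.44), the neighbouring X-chromosome genes STS (−2.50 ± 0.22) and PUDP (−2.43 ± 0.18), and HOXC4 (−2.37 ± 0.28). The FSTL5 value was −6.32 without parental replicate 3 and −4.80 without HRA replicate 2.

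Of 20 tested genes of nucleoside uptake and cytarabine metabolism, 3 rose and 1 fell in HRA, against 7 and 2 when adjusted over the list alone (list adjusted p = 0.576 with an estimated correlation). DCK, the kinase that makes cytarabine monophosphate, fell from 4043 ± 219 to 3193 ± 52.8 (log2 fold change −0.34 ± 0.09, SE, adjusted p = 0.0235). That call was lost without parental replicate 1 or 2 (adjusted p = 0.0537 and 0.0819) and without HRA replicate 1, 2 or 3 (adjusted p = 0.0737, 0.0767 and 0.0745). Over all alternatives its adjusted p ran from 0.00603 to 0.205. RRM1, the large subunit of ribonucleotide reductase, rose from 10035 ± 1092 to 13745 ± 898 (0.46 ± 0.10, adjusted p = 0.0144), a call lost without parental replicate 3 (adjusted p = 0.0510) or HRA replicate 2 (adjusted p = 0.0662, range over alternatives 0.00105 to 0.0662). The small subunit RRM2 had a log2 fold change of 0.46 ± 0.17 with an adjusted p of 0.0857, which became 0.0331 without parental replicate 2 and 0.0101 with the replicate number as a block (range 0.0101 to 0.271). The nucleoside transporter SLC29A1 (0.08 ± 0.12, adjusted p = 0.678), the nucleotide hydrolase SAMHD1 (0.22 ± 0.09, 0.118) and the nucleotidase NT5C2 (0.09 ± 0.09, 0.507) did not pass. CDA, the deaminase that inactivates cytarabine, had 1 read in all parental and 4 in all HRA libraries, too few to test.

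ABCC1 stood at 1799.7 ± 122 in parental cells and at 1917 ± 121 in HRA (adjusted p = 0.485), and 1 of 9 tested ABC efflux transporters and vault genes fell (1 adjusted over the list alone, list adjusted p = 0.755). That gene was ABCC2 (−1.14 ± 0.32, adjusted p = 0.0225), whose call was lost without parental replicate 3 (adjusted p = 0.0716) and without HRA replicate 1, 2 or 3 (0.0549, 0.0765 and 0.0608, range 0.0128 to 0.105). ABCB1, the P-glycoprotein gene, had 0, 1 and 2 reads in parental, HRA and HRD cells, and ABCG2 had 18, 14 and 24, so neither could be tested. Of 14 tested genes that lie next to ABCB1 on chromosome 7, 5 rose, among them MTERF1 (0.52 ± 0.09) and CDK14 (0.48 ± 0.09), and 10 rose when adjusted over the list alone (list adjusted p = 0.0948 with an estimated correlation). All of chromosome 7 was raised in HRA, with a median of 0.27 over 503 genes and running medians between 0.15 and 0.40, none past the limit of 0.556 for a stretch, while chromosome medians in 100 shuffled gene orders stayed between −0.04 and 0.03, so the rise was not confined to the genes next to ABCB1. Of 11 anthracycline targets and reducing enzymes, 3 rose and none fell by the limma test (3 higher and 2 lower adjusted over the list alone), with a list median of −0.05, a mean of 0.04 and a list adjusted p of 0.939. CBR1, a carbonyl reductase of anthracyclines, was among them, at 600 ± 56.4 in parental cells and 871 ± 77.9 in HRA (0.54 ± 0.11, adjusted p = 0.00707). It lies on chromosome 21, whose 108 tested genes had a median of 0.17 in HRA and 0.33 in HRD, with no stretch past the shuffled limits. TOP2A (−0.28 ± 0.10, adjusted p = 0.0882) and TOP2B (−0.15 ± 0.08, 0.254) did not pass.

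Myeloid genes moved in both directions in HRA. Of 15 tested primary granule genes of promyelocytes, 6 rose and 2 fell (7 and 2 adjusted over the list alone, list adjusted p = 0.753): lysozyme (LYZ) rose 2.19-fold to 6882 ± 380, NKG7 rose 2.58-fold and the ribonuclease RNASE3 2.32-fold. The serine protease CTSG fell 2.63-fold. MPO, the most abundant of these transcripts, did not pass (−0.16 ± 0.15, adjusted p = 0.506). Of 17 monocyte and macrophage genes, 4 rose (7 adjusted over the list alone, list adjusted p = 0.576), namely the Fc receptor FCGR1A (128 ± 21.6 to 723 ± 227, 5.50-fold), CTSB, CD4 and TLR4. CTSB lies on chromosome 8, which was raised along its whole length in HRA: of its 373 tested protein-coding genes 216 rose and 2 fell, with a median log2 fold change of 0.49 and running medians between 0.40 and 0.62. LPL, ZNF704 and CA2 lie on it too. Of 7 late neutrophil genes, 2 fell and none rose (3 lower adjusted over the list alone, list adjusted p = 0.576): CHI3L1 from 55.6 ± 28.4 to 2.21 and FPR2 from 28.1 ± 22.4 to 2.41 ± 0.31. Their log2 fold changes were −4.33 and −2.84, and they were −3.64 for CHI3L1 without HRA replicate 2 and −2.25 for FPR2 without parental replicate 3. CHI3L1 lies in a stretch of chromosome 1, from DUSP23 to PGBD2, where 353 tested genes had a median of −0.44 in HRA and −0.17 in HRD. Of 35 myeloid transcription factors, 8 rose and 1 fell (11 and 2 adjusted over the list alone, list adjusted p = 0.576), led by GFI1B (6 to 249 reads in 3 libraries, 4.75 ± 0.51), ETS1 (1.06 ± 0.20), CEBPA (0.63 ± 0.12) and, downwards, RUNX3 (−1.29 ± 0.17). CEBPA lies on chromosome 19, whose tested protein-coding genes had a median of 0.30 in HRA. PAX5 was the only 1 of 3 B cell genes to rise (325 ± 22.4 to 728 ± 34.8, list adjusted p = 0.576). CA2 was the only 1 of 5 erythroid and megakaryocyte genes to rise (0.739) and ACTA2 the only 1 of 4 fibroblast and epithelial genes, from 12.8 to 68.0 (0.576), with the same counts adjusted over the list alone except for 2 in the last list. Of 11 stem and progenitor genes 1 rose (CDK6, on chromosome 7, 1.02 ± 0.14) and 1 fell (2 and 2 adjusted over the list alone, list adjusted p = 0.753). Of 9 HOXA and HOXB genes 2 rose and 1 fell (the same adjusted over the list alone, 0.576), HOXA13, also on chromosome 7, upwards by 0.90 ± 0.14.

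Of 38 tested genes of double-strand break repair and replication stress, 12 rose and 2 fell (12 and 3 adjusted over the list alone, list adjusted p = 0.753 with an estimated correlation), with PRKDC (on chromosome 8), the catalytic subunit of DNA-dependent protein kinase, up from 10784 ± 1949 to 16699 ± 311, the checkpoint adaptor CLSPN (0.49 ± 0.10) and RPA2 (0.53) also up. Of 50 cell cycle and mitosis genes, 8 rose and 3 fell (8 and 4 adjusted over the list alone, list adjusted p = 0.843): the G1 cyclin CCND1 rose 7.19-fold from 77.4 to 549 ± 164. E2F2, CCNE1 and, on chromosome 8, CCNE2 and the replicative helicase gene MCM4 rose, while CENPF, in the chromosome 1 stretch, fell. CCNE1 lies on chromosome 19, where 152 of 766 tested protein-coding genes rose and 15 fell in HRA (median 0.30). Of 23 p53 targets 4 rose and 1 fell (the same adjusted over the list alone, list median −0.06, mean 0.07, adjusted p = 0.852), the fall being that of ZMAT3 (−0.67 ± 0.11). Among adhesion genes 8 of 25 rose and 1 fell (10 and 1 adjusted over the list alone, list adjusted p = 0.729), with PECAM1 up 4.80-fold to 204 ± 67.3, CD44 up from 9515 ± 707 to 15578 ± 2198 and the collagen receptor ITGA2 down (−1.28 ± 0.20). Of 22 NF-kB and inflammatory genes 6 rose (6 adjusted over the list alone, list adjusted p = 0.753), among them TNFAIP3 (1.55 ± 0.21) and the chemokine CCL5 (1.86 ± 0.30).

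None of the remaining lists passed the list test in HRA. Of 33 interferon-stimulated genes 4 rose and 2 fell (BST2, on chromosome 19, 0.94, IFITM2 −0.97, the same counts adjusted over the list alone, list adjusted p = 0.755). Of 17 MHC class I and antigen processing genes 4 rose (6 adjusted over the list alone, 0.605). Of 41 nuclear genes of oxidative phosphorylation 2 rose and 7 fell (2 and 8 adjusted over the list alone, 0.788), with SDHC down inside the chromosome 1 stretch and the chromosome 8 genes COX6C and UQCRB up. Of 28 NRF2 targets and antioxidant genes 6 rose and 2 fell (11 and 3 adjusted over the list alone, 0.753), MGST1 by 0.55 upwards and the glutathione synthesis gene GCLM by −0.66. Of 16 glutathione, metallothionein and detoxifying genes 4 rose and 2 fell (6 and 3, 0.753, MT1X 0.93). Of 8 NADPH oxidase subunits 1 rose and 1 fell (1 and 1, 0.753), the rise being that of CYBB (86.7 ± 6.94 to 344 ± 18.5). Of 16 TGF-beta and SMAD genes 4 rose and 1 fell (5 and 2, 0.771). In other lists 1 of 15 BCL2 family genes was higher (1 and 0, 0.753). There were 3 higher of 29 unfolded protein response and ATF4 genes (2 and 0, 0.788) and 2 higher of 25 immediate-early and heat-shock genes (0 and 0, 0.753). Next came 1 and 2 of 22 SUMO enzymes (1 and 4, 0.753), 1 and 1 of 18 replication-dependent histone genes (1 and 1, 0.755), 1 and 1 of 33 MYC targets (0 and 0, 0.788) and 1 lower of 13 mitochondrially encoded genes (0 and 1, 0.771), where each pair in brackets gives higher and lower genes adjusted over the list alone and then the list adjusted p. None of 27 glycolysis genes (0.939) or 23 cholesterol synthesis genes (0.784) was called by limma, either over all genes or over the list alone.

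In the limma test over 12569 genes, 1148 genes were higher and 767 lower in HRA than in parental cells, of which 273 and 139 differed at least 2-fold. At an unadjusted p below 0.05 there were 3929 genes. Of the 1915 called genes, 1911 had no overlap between the groups, and 38% of all tested genes had none, where chance gives 10%. Because same-numbered parental and HRA libraries deviated together, the fit with the replicate number as a block also applies. It called 1572 genes higher and 1202 lower, beside the 1148 and 767. Counts depended on single libraries: 576 and 575 genes were higher without HRA replicate 1 or 2, and 441, 328, 371 and 465 were lower without parental replicate 2 or HRA replicates 1, 2 or 3. By camera with an estimated correlation 0 of 34 lists passed, 2 had an unadjusted p below 0.05, and the preset correlation called 7 and the directional fry test 8.

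**Figure D1:**
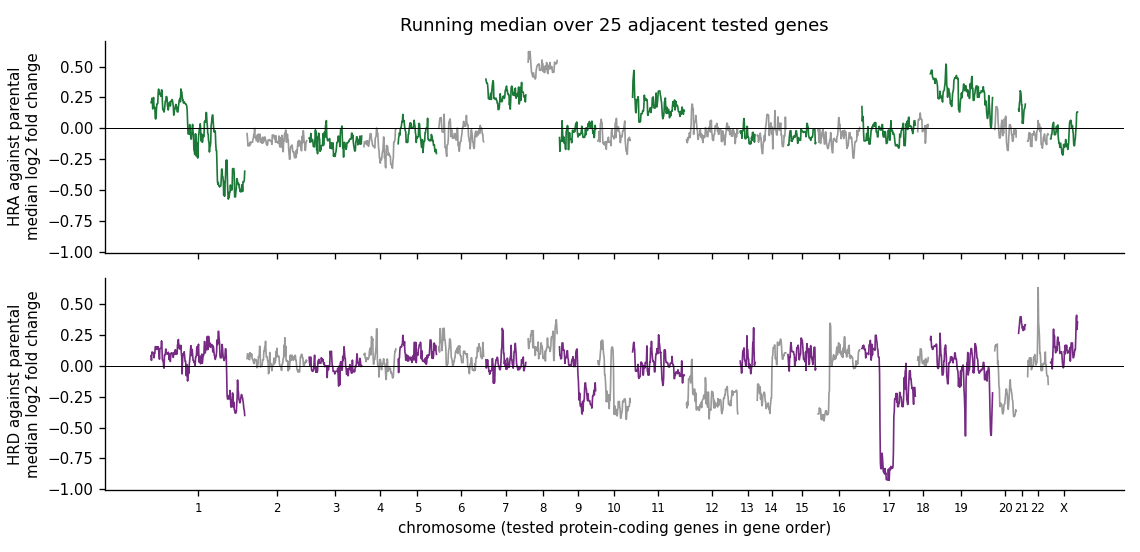
Median log2 fold change against parental cells of 25 neighbouring tested protein-coding genes (y axis) along each chromosome (x axis, genes in neighbour order), for HRA (top) and HRD (bottom), with 3 replicates per group. In HRA the stretch of chromosome 1 from DUSP23 to PGBD2 had a median of −0.44, and in HRD the stretch of chromosome 17 from TAOK1 to SCRN2 had one of −0.82.

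To find what accompanies daunorubicin resistance, HRD cells were compared with parental cells. ABCC1, which encodes the efflux pump MRP1 that carries anthracyclines out of cells, rose 26.5-fold, from a normalized read count of 1799.7 ± 122 to 47682 ± 2961 (log2 fold change 4.73 ± 0.08, SE, adjusted p = 1.80e-11). It was the only 1 of 9 tested efflux and vault genes to change (1 adjusted over the list alone, list adjusted p = 0.517). Its neighbours on chromosome 16 rose with it: FOPNL rose 27.7-fold to 89426 ± 6029, NDE1 rose 33.5-fold to 77131 ± 11080, NOMO3 by 5.52 ± 0.11 and KIAA0430 by 3.90 ± 0.11 on the log2 scale. TOP2A, the topoisomerase II isoform of dividing cells and a target of daunorubicin, fell 1.91-fold, from 30618 ± 3305 to 16041 ± 1614 (adjusted p = 1.05e-04). PSMD5, an assembly factor of the proteasome, fell from 2956 reads in the parental libraries to 1 read in the HRD libraries, and CYB5A, cytochrome b5, from 2588 reads to 2.

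The rise around ABCC1 took in 8 consecutive tested protein-coding genes, from NPIPA5 to NOMO3, all at least 4-fold higher in HRD. NPIPA5 is the weakest of them (2.41, adjusted p = 0.0352), and its call was lost without parental replicate 1 or 3 (0.112 and 0.0791) and without HRD replicate 1, 2 or 3 (0.0711, 0.0798 and 0.0922, range 0.0115 to 0.112). Its value was 1.72 without parental replicate 1 and 3.14 without parental replicate 2. MYH11, which lies in antisense overlap with NDE1, went from 3 to 866 reads, a ratio of 261 with a 95% counting interval of 88.9 to 1270. The strand setting of the counting is not stated, so reads of the pair cannot be told apart. NOMO3 and its near-identical copies NOMO1 and NOMO2 (2.93 ± 0.11) may exchange reads, so their separate values are uncertain. The nearest tested genes outside the run, RRN3 (−0.37 ± 0.09) before it and XYLT1 (−1.17 ± 0.12) after it, fell in HRD, and PDXDC1 did not pass (−0.22, adjusted p = 0.0516). Past XYLT1, ARL6IP1 (0.85 ± 0.11) and SMG1 (0.80 ± 0.12), which were chosen after their values were seen, rose. In HRA the log2 fold changes of the block genes ABCC1, FOPNL and NDE1 were 0.09, −0.22 and −0.11, none past the threshold. NOMO3 rose in HRA (0.43 ± 0.11, adjusted p = 0.0212), a call lost without parental replicate 3 (0.0575) and without HRA replicate 1 or 2 (0.0501 and 0.0888, range 0.0110 to 0.155). A FOPNL call appeared with the replicate block (adjusted p = 0.0288, range over alternatives 0.0173 to 0.366).

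**Figure D2:**
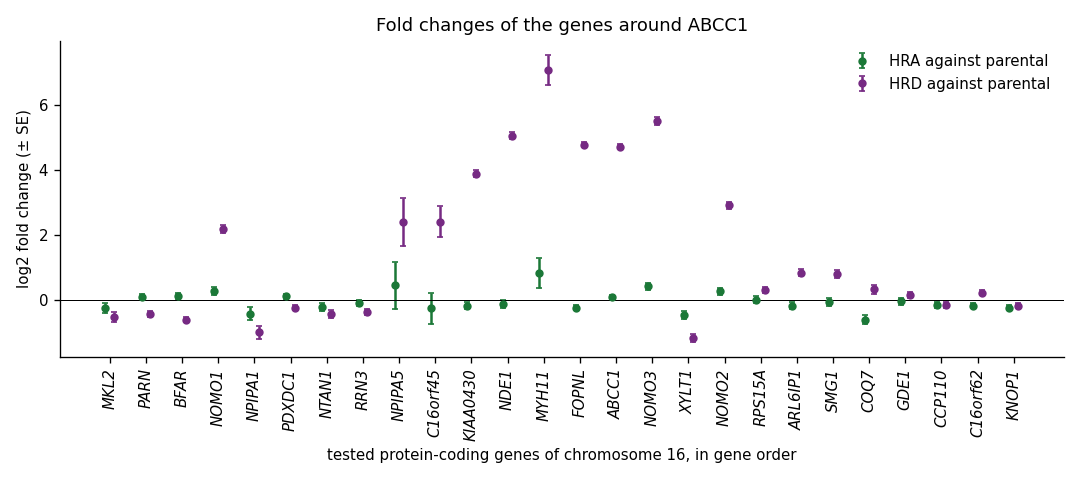
Log2 fold change against parental cells (y axis, bars show the SE) of 26 consecutive tested genes around ABCC1 on chromosome 16 (x axis, in neighbour order) in HRA and in HRD, with 3 replicates per group. In HRD the genes from KIAA0430 to NOMO3 lie between 3.90 and 7.09, while RRN3 lies at −0.37 and XYLT1 at −1.17, and in HRA ABCC1 lies at 0.09.

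A group of genes that parental cells express was close to 0 in HRD. At least 16-fold falls from a parental mean of 50 or more were found for 33 genes. Of these, 12 are zinc finger genes of chromosome 19, and HRA had 4 such genes in all. ZNF577 went from 396 reads to 0, which makes it at least 146-fold lower against a floor of 3 reads over the group. The fold was 3270 for PSMD5 (95% counting interval 587 to 129000), 1430 for CYB5A (396 to 11800), 1060 for ZNF260 (189 to 41700), 445 for the transcription factor NFATC2 (152 to 2160) and 564 for ZNF649 (101 to 22300). NCALD (−6.86 ± 0.22) and ZNF304 (−6.48 ± 0.34) kept 5 reads each. PSMD5-AS1, which overlaps PSMD5 in antisense, went from 641 reads to 0 and cannot be separated from it without a stated strand setting. ZNF260 and ZNF304 lie in stretches of chromosome 19 that were lower in HRD, from POLR2I to EIF3K (33 genes, median −0.35, which does not reach the shuffled limit of −0.473 for windows) and from ZNF444 to ZNF329 (35 genes, median −0.52). Both stretches hold zinc finger genes that fell, so their medians are not independent of the falls of that family. Among all 142 tested zinc finger genes of chromosome 19, 58 fell and 4 rose in HRD (median −0.33), while 7 fell and 16 rose in HRA (median 0.19). Apart from the block, the largest rises were those of SORCS2 (6.68 ± 0.68, from 7 to 930 reads), CLC (5.97 ± 0.32), BACH2 (5.44 ± 0.62), CCND1 (4.99 ± 0.28) and LTBP1 (4.93 ± 0.74). Single parental libraries set some of these sizes: the value without parental replicate 3 was 7.53 for SORCS2, 4.51 for BACH2 and 3.76 for LTBP1, and without parental replicate 2 it was 5.99 for SORCS2 and 5.69 for LTBP1.

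Among the drug lists in HRD, 3 of 11 anthracycline targets and reducing enzymes rose and 1, TOP2A, fell (the same adjusted over the list alone, list adjusted p = 0.535). TOP2A lies in a stretch of chromosome 17, from TAOK1 to SCRN2, in which 188 tested genes had a median log2 fold change of −0.82 in HRD and −0.03 in HRA. CBR1 rose from 600 ± 56.4 to 856 ± 56.2 (0.52 ± 0.11, adjusted p = 0.00579), and TOP2B did not pass (0.10 ± 0.08, 0.432). Of 20 nucleoside and cytarabine genes, 2 rose and 3 fell (the same adjusted over the list alone, list adjusted p = 0.819), with the UMP-CMP kinase CMPK1 down from 9050 to 5673 and the p53-inducible reductase subunit RRM2B up (0.53 ± 0.12). NT5C2 fell by 0.30 on the log2 scale (adjusted p = 0.0255), a call lost without parental replicate 2 or 3 (0.0676 and 0.0607) and without HRD replicate 2 or 3 (0.102 and 0.0528, range 0.0114 to 0.238). DCK did not pass in HRD (−0.16 ± 0.09, adjusted p = 0.219). Without HRD replicate 1 it did (0.0351, range 0.0351 to 0.709). None of these passed in HRD: RRM1 (−0.04), RRM2 (0.10), SLC29A1 (0.00) and SAMHD1 (0.14). Of 14 genes next to ABCB1, 3 rose (3 adjusted over the list alone, list adjusted p = 0.348), among them KIAA1324L (16.1 to 72.8). Of 15 BCL2 family genes 2 rose and 1 fell (the same adjusted over the list alone, list adjusted p = 0.682), with BCL2A1 up from 4.48 to 26.0. MCL1 rose by 0.31 ± 0.09 (adjusted p = 0.0240), lost without parental replicate 1 or 2 (0.0746 and 0.0546) or HRD replicate 1 or 2 (0.0560 and 0.0884, range 0.00507 to 0.194), and BCL2 did not pass (−0.06 ± 0.11, 0.760).

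Several granule, oxidase and neutrophil genes rose in HRD. CLC, which encodes the Charcot-Leyden crystal protein of eosinophils and basophils, rose 62.7-fold from 363 ± 198 to 21467 ± 6532. Of 15 primary granule genes 6 rose and 1 fell (7 and 1 adjusted over the list alone, list adjusted p = 0.446), with LYZ up 3.52-fold to 11028 ± 435, RNASE3 up 4.27-fold, RNASE2 up 2.40-fold and CTSG down 1.61-fold. MPO did not pass (−0.35 ± 0.15). Of 8 tested subunits of the NADPH oxidase, the enzyme of the respiratory burst, 5 rose and none fell by the limma test (5 adjusted over the list alone, list adjusted p = 0.348 with an estimated correlation): CYBB rose 9.60-fold to 853 ± 193, NCF4 4.14-fold to 908 ± 324 and NCF1 12.1-fold to 162 ± 86.9. NCF1 has near-identical pseudogenes, and NCF4 lies in a stretch of chromosome 22, from HMGXB4 to LGALS1, in which 27 genes had a median of 0.63, or 0.42 without the replicate 2 libraries, which is below the limit of 0.463 from shuffled gene orders. Of 25 late neutrophil genes 7 passed the filter and 4 rose (4 adjusted over the list alone, list adjusted p = 0.348): S100A9 from 13.5 ± 3.24 to 210 ± 89.0, S100A8 from 4 to 194 reads, MMP9 from 2.31 to 45.5 and CHI3L1. CHI3L1 went from 55.6 to 210 (1.99 ± 0.54, adjusted p = 0.0214), a call lost without parental replicate 1 or 2 (0.0672 and 0.0653) or HRD replicate 1 or 3 (0.0572 and 0.0678, range 2.49e-07 to 0.0678), and the MMP9 value of 3.85 was 3.14 without parental replicate 3 and 4.47 without HRD replicate 1. Of 17 monocyte and macrophage genes 6 rose and 1 fell (7 and 2 adjusted over the list alone, list adjusted p = 0.469), with the integrin ITGAX up from 63.2 to 198.

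**Figure D3:**
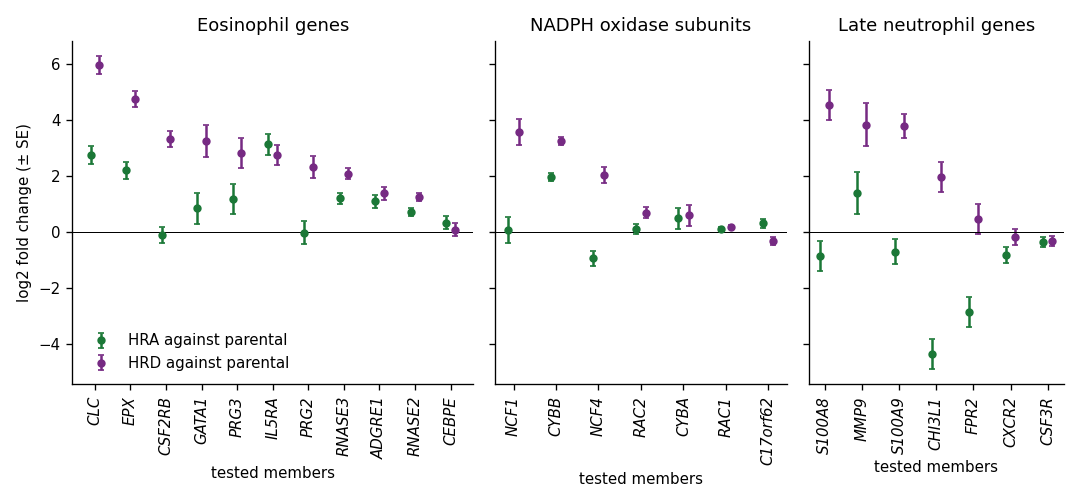
Log2 fold change against parental cells (bars show the SE, 3 replicates per group) of tested eosinophil genes, 7 of the NADPH oxidase subunits and late neutrophil genes in HRA and HRD. CLC lies at 2.76 in HRA and 5.97 in HRD, CYBB at 1.98 and 3.26, and CHI3L1 at −4.33 and 1.99.

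Transcription factors and markers of other lineages shifted as well in HRD. Of 35 myeloid transcription factors 10 rose and 5 fell (12 and 5 adjusted over the list alone, list adjusted p = 0.535): SOX4 rose from 663 ± 50.8 to 1226 ± 202, RUNX2 by 0.56 and the eosinophil and erythroid factor GATA1 from 3 to 63 reads, while RUNX1 fell by 0.35 on the log2 scale. Of 11 stem and progenitor genes 4 rose and 4 fell (4 and 5 adjusted over the list alone, list adjusted p = 0.966), with CDK6 up 2.33-fold. Of 27 erythroid and megakaryocyte genes 5 passed the filter and 2 rose (2 adjusted over the list alone, 0.388), CA2 and GATA1. Of 9 HOXA and HOXB genes 1 rose (HOXA11, 0.63, 1 adjusted over the list alone, list median 0.04 and mean −0.09, 0.819). Of 3 B cell genes 2 fell (2 adjusted over the list alone, 0.348), with the surrogate light chain gene IGLL1 down from 410 ± 64.1 to 31.7 ± 17.1. Of 20 fibroblast and epithelial genes 4 passed the filter and 3 rose (3 adjusted over the list alone, 0.348), with KRT8 up from 80.2 to 342 and FN1 from 6 to 278 reads. Most genes of these lists were too low to test, and the filter favours rises among genes that parental cells hardly express. Fewer than 3 T and NK cell markers and MHC class II genes passed the filter, so those lists were not tested.

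Cell cycle genes moved both ways in HRD: of 50 genes 6 rose and 9 fell (7 and 10 adjusted over the list alone, list adjusted p = 0.980). CCND1 rose 31.7-fold, from 77.4 to 2362 ± 362. CCND2, another D-type cyclin, fell 4.21-fold from 6683 ± 542 to 1599.6 ± 290, and the replication licensing gene CDC6, in the chromosome 17 stretch, fell 1.73-fold. Of 38 repair genes 3 rose and 4 fell (2 and 4 adjusted over the list alone, list adjusted p = 0.966), with BRCA1, also in that stretch, down from 4609 ± 430 to 2300 ± 58.4 and RAD52 down by 0.76 on the log2 scale. Of 28 NRF2 targets and antioxidant genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, list adjusted p = 0.348): besides ABCC1 these included the NADPH-producing enzymes ME1 (1.85-fold) and PGD, and the haem oxygenase HMOX1, from 8 to 110 reads, which lies in the chromosome 22 stretch. Of 42 replication-dependent histone genes 18 were tested, and 6 of these rose (6 adjusted over the list alone, 0.388), led by HIST1H2BD (1.47 ± 0.20) and HIST1H1C (1.43 ± 0.23). Only polyadenylated RNA was selected, so these values do not cover histone transcripts that are not polyadenylated. Of 25 adhesion genes 8 rose and 2 fell (9 and 2 adjusted over the list alone, 0.469), with ITGB2 up 2.81-fold and PECAM1 up 4.78-fold.

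Immune response lists in HRD held 7 of 17 MHC class I and antigen processing genes that rose (9 adjusted over the list alone, list adjusted p = 0.495), with B2M up from 35542 ± 3991 to 55836 ± 4788 and PDIA3 up 1.46-fold. There were 8 of 33 interferon-stimulated genes that rose with 4 that fell (11 and 4 adjusted over the list alone, 0.535), of which USP18 rose by 1.01. Of 22 NF-kB and inflammatory genes 5 rose (6 adjusted over the list alone, 0.471), the chemokine CXCL8 12.7-fold, from 549 ± 410 to 6386 ± 3017. Of 23 p53 targets 3 rose and 4 fell (5 and 5 adjusted over the list alone, 0.899), with TIGAR down by 0.53 on the log2 scale. In the rest of the lists the counts of higher and lower genes, with those adjusted over the list alone and the list adjusted p in brackets, were 6 and 0 of 25 immediate-early and heat-shock genes (6 and 0, 0.388), 4 and 0 of 16 TGF-beta and SMAD genes (4 and 0, 0.388) and 5 and 1 of 16 glutathione and metallothionein genes (5 and 1, 0.517). They were 4 and 1 of 29 unfolded protein response and ATF4 genes (3 and 1, 0.980), 4 and 0 of 41 oxidative phosphorylation genes (0 and 0, 0.825), 2 and 2 of 22 SUMO enzymes (0 and 2, 0.881) and 2 and 0 of 23 cholesterol genes (0 and 0, 0.655). The last were 1 and 1 of 27 glycolysis genes (0 and 0, 0.980), 0 and 2 of 33 MYC targets (0 and 2, 0.881) and 0 and 0 of 13 mitochondrially encoded genes (0 and 0, 0.980).

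The limma test called 1350 genes higher and 1513 lower in HRD than in parental cells, of which 429 and 295 differed at least 2-fold, and 4409 genes had an unadjusted p below 0.05. Of the 2863 called genes 2809 had no overlap between the groups, and 35.3% of all tested genes had none (chance 10%). Without HRD replicate 2 the higher count was 898. No list passed camera with an estimated correlation (0 of 34, 4 at an unadjusted p below 0.05), while the preset correlation called 17 lists and directional fry 14.

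**Figure D4:**
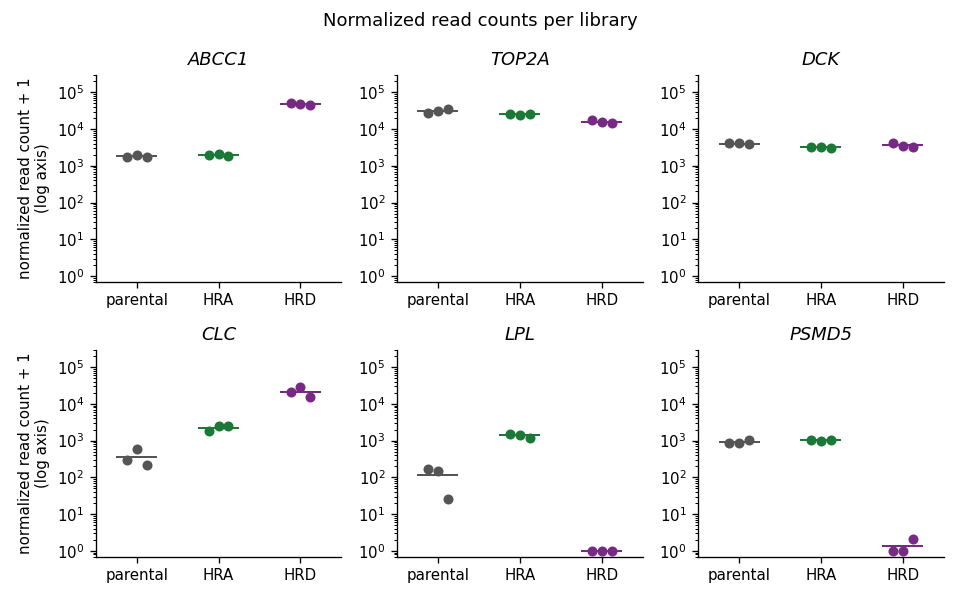
Normalized read count plus 1 (log axis) of ABCC1, TOP2A, DCK, CLC, LPL and PSMD5 in each of the 9 libraries, with points for libraries and lines for the means of 3 replicates. ABCC1 lies near 1917 in HRA and 47682 in HRD, and LPL and PSMD5 lie near 0 in HRD.

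HRD cells were then compared directly with HRA cells to find what separates the resistant states. ABCC1 was 24.9-fold higher in HRD than in HRA (log2 difference 4.64 ± 0.08, SE, adjusted p = 2.24e-11), FOPNL was 32.4-fold and NDE1 36.3-fold higher. Lipoprotein lipase (LPL) was at 1384 ± 157 in HRA and at 0 reads in HRD, at least 1690-fold lower. ACTL8, an actin-like gene expressed in testis, was at 10.3 ± 4.84 in HRA and 1743 ± 315 in HRD (7.33 ± 0.36), PLCB1, a phospholipase C, at 1.99 and 171, and SORCS2 at 2.68 ± 2.37 and 269 ± 31.3 (6.38 ± 0.68).

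Most other genes with the largest differences also differed between HRD and parental cells. MYH11 (6.26 ± 0.46) and NOMO3 (5.09 ± 0.11) were higher in HRD, as was CHI3L1 (6.32 ± 0.54, 5.63 without HRA replicate 2). Zinc finger genes ZNF714 and ZNF614 had 817 and 572 reads in HRA and 0 in HRD, at least 329-fold and 230-fold lower. The ratio of HRA to HRD was 3660 for PSMD5 (95% counting interval 657 to 145000), 1620 for CYB5A (448 to 13400), 1930 for ZNF260 (345 to 76200), 528 for NFATC2 (180 to 2560) and 570 for ZNF649 (102 to 22600). TOP2A was lower in HRD than in HRA (−0.65 ± 0.10, adjusted p = 9.96e-04), as were RRM1 (−0.50 ± 0.10, 0.00472) and CMPK1 (2.00-fold), and NT5C2 was lower (−0.39 ± 0.09, 0.00590) and MCL1 higher (0.40 ± 0.09, 0.00580). For DCK (0.18 ± 0.09, 0.138), RRM2 (−0.37 ± 0.17), CBR1 (−0.02, 0.890), BCL2 (−0.19, 0.193) and MPO (−0.19, 0.357) the difference did not pass. MYC differed neither in HRA (0.24 ± 0.12, 0.191) nor in HRD (−0.08 ± 0.12, 0.699) from parental cells nor between them (−0.32 ± 0.12, 0.0639), and the stem cell marker CD34 had only 10, 15 and 21 reads in parental, HRA and HRD cells.

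Between the resistant lines, 13 of 38 repair genes were lower and 5 higher in HRD (6 higher and 13 lower adjusted over the list alone, list adjusted p = 0.935): BRCA1 was 2.63-fold lower and XRCC2, MRE11 and PRKDC were lower. TDP2, which removes trapped topoisomerase II from DNA, and LIG4 were higher. Of 7 late neutrophil genes 5 were higher in HRD (5 adjusted over the list alone, list adjusted p = 0.183 with an estimated correlation), with S100A9 at 8.83 in HRA and 210 in HRD and FPR2 at 2.41 and 36.0. Of 8 NADPH oxidase genes 5 were higher and 1 lower (the same adjusted over the list alone, 0.628), CYBB 2.43-fold and NCF4 7.87-fold. Of 50 cell cycle genes 13 were higher and 12 lower (13 and 16 adjusted over the list alone, 0.969), with CCND2 3.23-fold, E2F2 1.97-fold and CDC6 2.03-fold lower and the mitotic kinase PLK1 (0.85 ± 0.11) and CCND1 (2.14 ± 0.28) higher. All 3 tested B cell genes were lower in HRD (3 adjusted over the list alone, 0.183), PAX5 by 1.37 and IGLL1 by 3.40 downwards on the log2 scale. Of 35 myeloid transcription factors 7 were higher and 9 lower (7 and 11 adjusted over the list alone, 0.935), CEBPA 2.07-fold and ETS1 2.69-fold lower and RUNX3 2.40-fold higher.

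For this direct comparison limma called 1749 genes higher and 2038 lower in HRD than in HRA (367 and 425 at least 2-fold, 5283 at an unadjusted p below 0.05), and 3744 of the 3787 called genes had no overlap between the groups, with 47% of all tested genes having none (chance 10%). Which direction had more genes depended on the scaling: with equal totals 2067 genes were higher and 1739 lower (share higher 54.3% instead of 46.2%), and with quantile normalization 2037 and 2023. Without HRA replicate 1 the counts were 1049 higher and 1342 lower. Camera with an estimated correlation called 0 of 34 lists (2 at an unadjusted p below 0.05), the preset correlation 4 and directional fry 10.

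Some genes moved in the same direction in both resistant lines. CCND1 rose 7.19-fold in HRA and 31.7-fold in HRD, CDK6 2.03-fold and 2.33-fold, CLC 6.76-fold and 62.7-fold, and SUCNR1 by 4.46 and 2.54 on the log2 scale, while IGFBP2, GIMAP6 and FSTL5 fell in both. The extent differed between HRD and HRA for CCND1 (2.14, adjusted p = 3.15e-04), CLC (3.21, 4.57e-05), SUCNR1 (−1.93, 1.35e-04) and GIMAP6 (−2.95, 6.94e-04). For CDK6 the difference did not pass (0.20, adjusted p = 0.319) except without HRD replicate 2 (0.0183, range 0.0183 to 0.768). In all, 393 genes were higher in both lines and 208 lower in both, where independent lists of those sizes would share 123.3 and 92.3. With the replicate number as a block 588 were higher and 371 lower in both. Both comparisons use the same parental libraries, so part of the excess may come from these, which cannot be split with at least 2 libraries on each side. In 100 simulations of unchanged groups against shared parental libraries, the fold changes of all genes correlated at 0.504 on average and the covariance was 0.0272, against an observed correlation of 0.341 across genes and a covariance of 0.1253, a covariance difference of 0.0982. Genes are not independent replicates. In opposite directions, 67 genes were higher in HRA and lower in HRD than in parental cells and 54 the reverse. The number higher in both was 212 and 221 without HRA replicate 1 or 2, and the number lower in both was 118 and 133 without parental replicate 2 or 3 and 106, 125 and 138 without HRA replicate 1, 2 or 3. A moderated F test over all 3 groups called 4785 genes, 38.1% of those tested.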

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

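The splits of the gene calls, the tests of the block around ABCC1, the covariance over library pairs, and the depth and zinc finger enrichment tests of the genes near 0 were chosen only after these results were seen.

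Around ABCC1, 8 consecutive genes were at least 4-fold higher in HRD, where the longest such run in shuffled gene orders was 3. Within this run 5 genes without near-identical copies, KIAA0430, NDE1, MYH11, FOPNL and ABCC1, had a median log2 fold change of 4.79. Reads shared between copies therefore do not explain their rise. C16orf45, at 2.42, was not among the 5. The median over all genes was 0.008, which decides nothing, because scaling by the median of ratios holds it near 0. Scaling moves all genes of a library alike, however, and the nearest tested genes outside the run, RRN3 (−0.37) and XYLT1 (−1.17), were not raised. The scaling of the libraries therefore does not set the run apart from them. A change of 1 chromosomal segment, such as an amplification, could account for the run, but copy number was not analysed here. Genes past XYLT1, such as ARL6IP1 (0.85), rose as well. The members MYH11 and NDE1 overlap in antisense, and the calls of NPIPA5 depend on single libraries.

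The 33 genes near 0 in HRD were not a matter of depth, since the pooled HRD depth was 110.3% of the parental depth. Of the 33 genes, 29 were protein-coding genes with a place in the neighbour order. Of their 58 nearest expressed neighbours, 12 (20.7%) were also at least 16-fold lower. Adjacent near-0 genes were counted from both sides, so the 95% interval of 11.2% to 33.4% treats linked items as independent. This leaves open whether lost stretches of DNA may have a part. The summed rise of the 4 chromosome 19 zinc finger genes called higher was 59.0% of the summed fall of the 12 near-0 ones (897.29 beside 1521.9). That fall leaves out the others among the 58 chromosome 19 zinc finger genes called lower. The test therefore cannot tell whether reads assigned to similar genes have a part in the zinc finger falls. The near-0 genes held chromosome 19 zinc finger genes at an odds ratio of 65.1 (Fisher exact p = 1.94e-16, lower limit 31.5) against expressed protein-coding genes. This class was chosen after it was seen among them, and adjacent members count as independent, so the p-value decides nothing. A selective loss of the expression of these zinc finger genes would give such an enrichment, and the tests cannot tell it from the other causes.

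The covariance of the fold changes of HRA and HRD against parental cells was 0.1253, above the highest value of 0.0306 in 100 simulations, so the shared parental libraries alone do not explain it. Culture states that add equally to the same-numbered libraries of all groups cancel in these comparisons, and without the replicate 2 libraries the covariance was 0.1297, while same-direction calls fell from 601 to 255 with fewer libraries. The correlation in that setting (0.345 beside 0.341), which was the test set beforehand, decides nothing, because shared parental libraries alone gave 0.504 on average. Over 6 pairs of single-library fold changes that share no library and no replicate number, the covariance was 0.0962 on average, which goes against such states as the whole cause. But the lowest pair (0.0466) was below the bound of 0.0491, which was chosen with this test after the results were seen. States that act differently in each group therefore stay open, and a common effect of long culture in either drug was not tested.

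The number of genes called was the highest for the real grouping in each comparison, at 1 of 10 splits, with 1915, 2863 and 3787 genes beside at most 0, 114 and 0 in other splits. With 10 splits no share below 0.05 can be reached. In the F test the real grouping was 1 of 100 splits, with 4785 genes beside at most 1125. For the gene lists 10 of 10 splits called as many as the real grouping, namely 0.

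Some genes were called in opposite directions against parental cells and the difference was tested directly. LPL differed by −10.43 between HRD and HRA (4.02 in HRA and −6.41 in HRD against parental), ZNF260 by −8.87 (0.86 and −8.01), ACTL8 by 7.33 (−2.90 and 4.43), CHI3L1 by 6.32 (−4.33 and 1.99), PLCB1 by 6.0 (−2.12 and 3.88) and ZNF614 by −7.57 (1.92 and −5.65). LPL and ZNF614 had 0 reads in HRD, so their values, which come from log2(value + 1), understate the falls: these were at least 1690-fold and 230-fold against HRA and at least 161-fold and 82.7-fold against parental cells. ZNF260 had 1 read there, a ratio of 1930 against HRA (95% counting interval 345 to 76200). Without parental replicate 3 the values against parental cells were 3.13 in HRA and −7.30 in HRD for LPL and 1.21 and −6.35 for ZNF614. The rise of ZNF260 in HRA was lost without any 1 of the parental and HRA libraries (adjusted p 0.0610 to 0.113), that of ZNF614 without HRA replicate 1, 2 or 3 (0.0859, 0.0620 and 0.0775), the fall of PLCB1 without HRA replicate 1 (0.0640), and the rise of CHI3L1 in HRD without parental replicate 1 or 2 or HRD replicate 1 or 3 (0.0672, 0.0653, 0.0572 and 0.0678).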

How the results depend on the processing

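The setting without the replicate 2 libraries and the thinning of reads were chosen only after the results were seen.

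Of 557 named gene results 200 changed side of the threshold in at least 1 alternative and 0 reversed. With a minimum value of 50, the genes at least 2-fold higher and lower numbered 181 and 86 in HRA, 261 and 196 in HRD, and 213 were higher in HRD than in HRA. With the replicate number as a block 1572 genes were higher and 1202 lower in HRA, and 588 were higher and 371 lower in both lines. That block also gave 1744 higher and 1895 lower genes in HRD, and 2257 higher and 2416 lower in HRD than in HRA.

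Leaving out 1 library at a time moved the genes higher in HRA between 575 and 1352, those lower between 328 and 965, those higher in HRD between 898 and 1335, and the genes of the direct comparison between 1049 and 1848 and between 1342 and 2085. Genes higher in both lines ran from 212 to 436 and genes lower in both from 106 to 289. Without the replicate 2 libraries 481 and 231 genes were called in HRA, 740 and 730 in HRD, 765 and 1060 between the lines, 198 and 57 in both lines, and 2239 by the F test. That replicate had 17 of 18 hypoxia-inducible genes highest in every group.

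Camera with the preset correlation called 7, 17 and 4 lists in HRA, in HRD and between the lines, where the estimated correlation called 0. Directional fry, which tests a list against no change and not against other genes, called 8, 14 and 10. edgeR called 1924, 2852 and 3800 genes, DESeq2 2366, 3144 and 4105, and reads thinned to the shallowest library gave 1754, 2683 and 3518. With equal totals the share of higher genes in HRA was 51.7% instead of 59.9%, and between the lines it was 54.3% instead of 46.2%.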

Other observations

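The list of eosinophil genes, the chromosome stretches and medians and the hypoxia-inducible genes were chosen only after the results were seen.

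Of 11 tested eosinophil genes, 10 rose in HRD and 6 in HRA. The list was made after CLC and other such genes were seen to rise, so its camera test (adjusted p = 0.00968 in HRD and 0.102 in HRA, adjusted over the 3 lists added in this way and not over the 34) is run on genes chosen for the pattern and decides nothing. EPX, the eosinophil peroxidase, rose 27.1-fold in HRD, from 217 to 5655 ± 1817, and by 2.21 on the log2 scale in HRA. The receptor gene IL5RA rose in both lines (3.14 in HRA and 2.77 in HRD) and CSF2RB (3.32) in HRD, and PRG2 went from 17058 to 84628. RNASE2 and RNASE3 are also in the primary granule list.

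The next genes were picked after their values were seen, and no list of their kind was tested. CPT1A, which brings fatty acids into mitochondria, fell 12.5-fold in HRD, from 2407 ± 243 to 194 ± 39.0. SLC22A16, a carnitine transporter that also takes up anthracyclines, was lower in HRD than in parental cells (−3.66) and lower than in HRA (−5.06). The transcription factor gene CREB5 fell 50.9-fold in HRD.

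Stretches of neighbouring genes moved together, found where running medians passed the limits of shuffled gene orders (0.556 and −0.331 in HRA, 0.463 and −0.473 in HRD). In HRA 199 of 353 genes of chromosome 1 from DUSP23 to PGBD2 fell, and 216 of 373 genes of chromosome 8 rose, with the highest stretches from CLN8 to TNFRSF10B (median 0.56, 0.54 without the replicate 2 libraries) and from JRK to OPLAH (0.57 and 0.47). Without those libraries both medians lay below the limit of 0.556 from the main fit. The same held with quantile normalization (0.54 and 0.53) and with equal totals (0.52 and 0.54). In HRD 141 of 188 genes of chromosome 17 from TAOK1 to SCRN2 fell, TOP2A and BRCA1 among them, as did 14 of 33 genes of chromosome 19 from POLR2I to EIF3K and 21 of 35 from ZNF444 to ZNF329. Both chromosome 19 stretches hold zinc finger genes that fell, so they are not independent of the falls of that family. No stretch passed on chromosomes 7 and 19 in HRA or on chromosomes 10, 12, 20 and 21 in HRD. Their medians over all genes, 0.27 and 0.30 in HRA and −0.22, −0.28, −0.22 and 0.33 in HRD, lay outside those of 100 shuffled gene orders, which ran at most from −0.10 to 0.10. This was not particular to these chromosomes. Many other chromosome medians lay outside their shuffled ranges too, such as those of chromosomes 4 (−0.15) and 11 (0.17) in HRA and 8 (0.16) and X (0.13) in HRD. Some shifts had the same direction in both lines. In HRA and HRD the medians were −0.44 and −0.17 for the chromosome 1 stretch, 0.49 and 0.16 for chromosome 8 and 0.17 and 0.33 for chromosome 21. Other chromosomes moved apart, such as chromosome 4 (−0.15 and 0.05). The part of such shifts in the calls shared by both lines and in the covariance was not tested. DNA copy number was not analysed here.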
